A study of Mus musculus with 9 samples.

How the data were processed

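RNA was measured in 9 mouse libraries, 3 labelled mCherry, 3 labelled c-fos and 3 labelled overlap. The design text of the series describes a search for differential genes among cells labelled for CRD, for His and for both. The labels do not say which of CRD and His belongs to mCherry and which to c-fos, so the groups keep the names mCherry, c-fos and overlap throughout. Per the labels' protocols, cells were taken from fixed frozen tissue by laser capture microdissection and lysed directly, and libraries were made with Smart-3SEQ, a method that sequences the 3' ends of polyadenylated RNA. The series title places the study in the basolateral amygdala (BLA), while the labels' cell type and extraction text name spermatocytes and testis. Marker lists for both were therefore fixed beforehand. The labels tie no sample to an animal, and the number of animals is not given in the sources used here. If libraries of the same group share an animal, p-values over them are too small. If libraries of different groups do, the tests ignore a pairing, and p-values may be too small or too large. In any case p-values measure only the spread between these samples, which may be technical.

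The deposited table holds whole-number counts per gene and library, with no normalization visible in the values. Per the submitters' processing notes, Trim Galore, STAR, UMI-tools and featureCounts were used with genome build mm9. Their versions, order and settings are not given in the sources used here, nor is whether the counts were collapsed by molecular identifier or assigned by strand. Intervals and floors therefore cover counting error only, and reads of a gene cannot be told from those of a gene that overlaps it. Of the entries chosen by the naming rule given below, each gene counted once per contrast, 55.9% overlapped another annotated gene. The table holds 54838 Ensembl identifiers, of which 54723 were given a symbol from a table of gene names. The other 115 held 0.222% of all counts and stayed in the library sizes. All columns of the table were matched to a sample by name. The reference annotation at hand belongs to another build than mm9, so it was used for names, gene types and overlaps, and no coordinates are given. The 37 genes of the mitochondrial genome held 0 counts in every library, so the mitochondrial share of reads was not analysed here.

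Total counts ran from 90091 to 429317 per library, 2199270 in all. A floor of 3 counts corresponded to 33.3 CPM (counts scaled to a common library total) in the shallowest library and to 6.99 CPM in the deepest. Genes were also counted after thinning every library to 90091 counts. A fold against a group at 0 counts is given as a lower bound against the floor of 3 counts over the summed group. With 1 to 3 counts the ratio is given with its exact binomial 95% interval or is left out.

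All 9 libraries entered 1 fit of the deposited counts with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood test, Benjamini-Hochberg adjustment, adjusted p under 0.05). The 3 contrasts and a test for any group difference were taken from that fit, which held 7959 genes. The common dispersion was 0.735, a biological coefficient of variation of 0.857. Errors of log2 fold changes are standard errors derived from the fold change and its F statistic. Levels of single genes are TMM-scaled CPM unless stated otherwise, with SD over 3 libraries. Summed levels of lists, markers and insulin transcripts are CPM of the total count. These sums and their exact tests were not repeated with TMM scaling. The 29 gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 tested genes, adjusted over the 22 lists of a contrast. Each list was tested again with an estimated correlation and with fry, whose directional p does not compare a list with other genes. All tests were two-sided. Comparisons of single values between groups used exact permutation tests, which cannot give a p under 0.1 with 3 libraries against 3. The similarity of libraries was tested over all 280 splits of the 9 samples into 3 groups of 3.

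The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule names Fgf2, Notch2 and Fos. It then takes up to 10 genes per direction and contrast, those past the threshold with non-overlapping groups first, filled up with non-overlapping genes of smallest unadjusted p. It last takes up to 4 tested members per list with the smallest unadjusted p. Predicted genes and pseudogenes were counted but not named. The limitation of list members to those with an unadjusted p under 0.05 was added after values had been seen and the text names some of the genes this leaves. The immediate early gene list without Fos, the count of calls carried by 1 library, the medians under each scaling, and a self-test with lower dispersion were also added after values had been seen.

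The fits were tested on simulated counts drawn for the 7959 genes, with 200 genes changed. At the dispersion of these data, 13.6% of genes changed 8-fold were called in the simulation of c-fos against mCherry, 9.09% for overlap against mCherry and 10.6% for overlap against c-fos. For 4-fold changes the shares were 1.49%, 0% and 2.99%, and for 2-fold changes 0% in each. With the dispersion scaled by 0.1, the shares for 8-fold changes were 93.9%, 92.4% and 86.4%. A list shifted by 1.5 on the log2 scale was called by camera in each of the 3 simulations. With the estimated correlation and with fry it was missed in that of c-fos against mCherry. Genes were drawn independently, so the simulations cannot show how camera behaves with correlated genes. In the data the correlation of the immediate early genes was estimated at 0.0539.

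Alternatives set beforehand were DESeq2 size factors, upper quartile scaling, no filter, a filter of at least 10 counts in every library of a group, DESeq2 1.42.0, limma-voom with sample weights, a robust edgeR fit, the replicate number as a block, each replicate left out in turn, and fits of only the 2 groups compared. Leaving out the libraries mCherry 3 and overlap 1, which were rich in insulin transcripts, and a scale set on the 200 most abundant genes were chosen after seeing the data. Libraries with the same number showed little shared deviation, so the numbers were not taken to pair samples. A pairing or a shared batch is not excluded by this. A test of whether the insulin-rich libraries held another sample than labelled is not reported here.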

Results

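Transcripts of laser-captured cells were counted in 9 libraries, 3 each from cells labelled mCherry, c-fos and overlap, to find genes that differ among the groups. Total counts were 296052 ± 119387 (SD, n = 3) for mCherry, 237476 ± 111222 for c-fos and 199562 ± 99047 for overlap, with an exact permutation p of 0.554 over the 3 groups. At an equal depth of 90091 counts, 11056 ± 1521 genes were detected in mCherry, 12792 ± 425 in c-fos and 10949 ± 1205 in overlap (exact permutation p = 0.175 over the 3 groups). Every c-fos library lay above every other library in this number (exact permutation p = 0.1 against each group, the smallest possible). Meg3, a maternally expressed long noncoding RNA abundant in neurons, was the most abundant gene in 7 of the 9 libraries. Averaged over pairs of libraries, the Spearman correlation across genes was 0.435 within and 0.372 between groups. The difference of 0.0632 had an exact permutation p of 0.00714 over 280 splits. The order did not hold for overlap libraries, whose mean correlation with each other, 0.298, lay below those with c-fos, 0.365, and with mCherry libraries, 0.316. It was 0.481 among c-fos and 0.528 among mCherry libraries.

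Libraries mCherry 3 and overlap 1 stood apart. Insulin transcripts (Ins1 and Ins2, summed) reached 8106 CPM in mCherry 3 and 19647 CPM in overlap 1, against 247 to 990 CPM in the other 7. Ins1 and Ins2 are close paralogs whose reads may be shared. These libraries are left out again beside each count of genes, as an alternative chosen after seeing the data.

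The first comparison asked how cells labelled c-fos differed from cells labelled mCherry. Immediate early genes, which neurons induce within minutes of activity, were higher in c-fos cells as a group. Of the 23 tested members, 21 had positive fold changes, with a median log2 fold change of 2.02. Summed over all 35 genes of the list, their level was 4429.7 ± 862 CPM in c-fos and 1492 ± 140.3 CPM in mCherry, 2.97-fold higher, with every c-fos library above every mCherry library (exact permutation p = 0.1, the smallest possible). Egr1, an activity-induced transcription factor, had 590.4 ± 189.7 CPM against 103 ± 7.66 (log2 fold change 2.52 ± 0.58), and Npas4, another, had 165 ± 68.0 against 7.60 ± 13.2 (4.29 ± 1.20). Nr4a3 (2.59 ± 0.72) and Jun (2.65 ± 0.83) were of similar size, none of these passing the test over all genes in edgeR.

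The list was called by camera at an adjusted p of 3.13e-11, at an adjusted p of 0.0402 with an estimated correlation, and at 0.0068 by fry. Adjusted over the list alone, 6 members were higher and 0 lower, and over all genes 0 in edgeR. The label c-fos names the product of Fos, a member of the list, so Fos (352 ± 42.4 against 103 ± 73.0 CPM, 1.76 ± 0.65) is no finding between these groups. Without it, 20 of 22 members were positive, with adjusted p = 1.43e-10, and 0.0433 with an estimated correlation. Leaving out Fos alone does not make the list independent of the label, since its other members are activity-induced too. The labelling itself may set the direction of the whole list, which was not tested. Summed markers of GABAergic neurons stood at 681 ± 126 CPM in c-fos and 342 ± 122 in mCherry, those of striatal projection neurons at 721 ± 138 and 467 ± 163, and those of basolateral amygdala subregions at 938 ± 31.4 and 779.9 ± 71.0 (exact permutation p = 0.1 for each). These sums are scaled to total counts. The TMM factor was 0.650 in mCherry 3, against 0.969 and 1.02 in mCherry 1 and 2, so TMM scaling would raise its sums relative to theirs. The striatal and basolateral amygdala separations therefore need not hold on the TMM scale. Genes detected at equal depth were also higher in every c-fos library than in every mCherry library, 12792 ± 425 against 11056 ± 1521 (exact permutation p = 0.1).

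**Figure D1:**
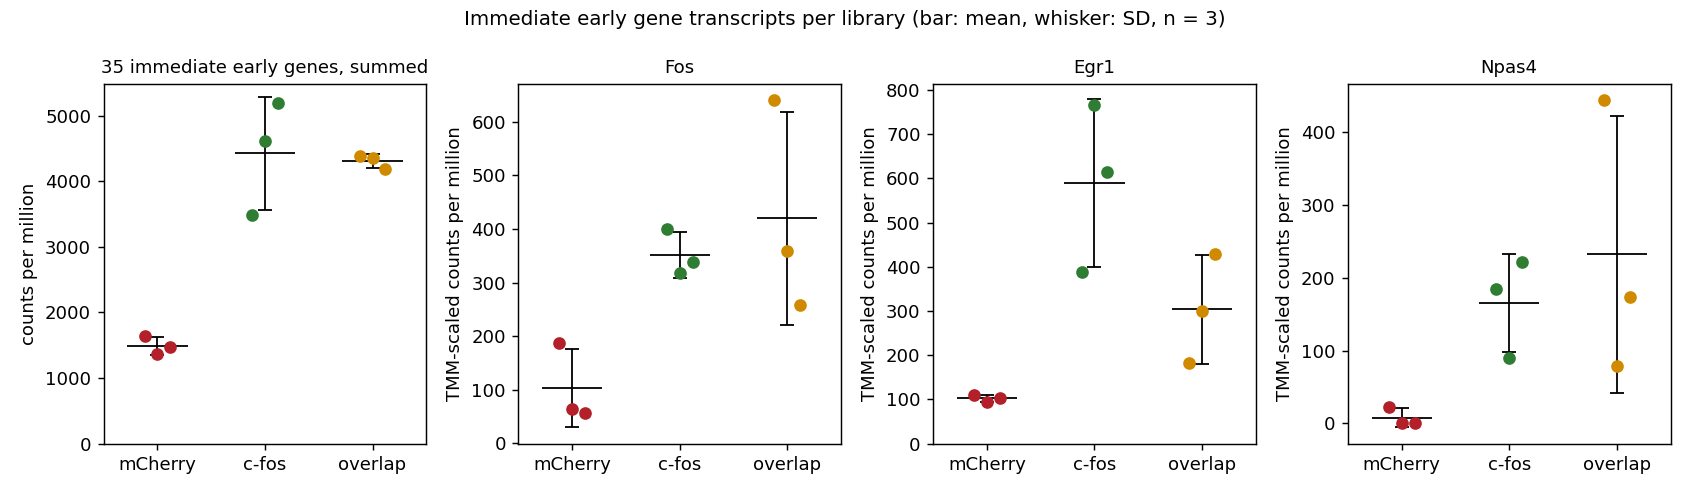
Level of immediate early gene transcripts in each library, in CPM of the total count for the summed list of 35 genes and in TMM-scaled CPM for Fos, Egr1 and Npas4 (points, libraries; bars, mean; whiskers, SD; n = 3). Summed levels lay between 1365 and 1642 in mCherry, 3492 and 5188 in c-fos, and 4184 and 4384 in overlap.

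No gene passed the test between c-fos and mCherry in edgeR, while 632 had an unadjusted p under 0.05 where chance gives 398. DESeq2 called 3 genes, Hesx1, Egr1 and Nipsnap3a, and limma-voom 8, with Hesx1, Egr1, Nptxr, Ptms, Olfm1 and Frrs1l among them. The groups did not overlap for 15.8% of genes, where chance gives 10%. Hesx1, a homeobox transcription factor of the developing forebrain and pituitary, had the smallest adjusted p, 0.0678. Its level was 364 ± 72.7 CPM over 218 counts in c-fos and 0 in mCherry, at least 79.5-fold higher. Upper quartile scaling, the stricter filter and the fit without mCherry 3 each called 1 gene, Hesx1, as did leaving out mCherry 3 and overlap 1 together.

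Of the 200 most abundant genes, 169 had negative fold changes in this comparison, with a median of -0.37. Single abundant genes may share this shift. The genes named next did not pass in edgeR. Among those with lower values in c-fos cells, Olfm1, a secreted neuronal glycoprotein, had 1316 ± 220 against 2987 ± 584 CPM (log2 fold change -1.18 ± 0.28), and Nptxr, the neuronal pentraxin receptor, 966 ± 52.5 against 2526 ± 167 (-1.39 ± 0.34). Nptxr shares its strand with Npcd. Frrs1l, an AMPA receptor assembly factor, stood at -1.17 ± 0.31, and Ptms, parathymosin, at -2.06 ± 0.42. Rabgap1 stood at -1.94 ± 0.53. Nipsnap3a, Fbxw28, Hipk2, Plscr5 and Rhot1 also had lower values, but their SD in mCherry exceeded the mean, as for Rhot1 with 743 ± 1114 CPM. Further genes with higher values included Tnfsf13b (at least 14.2-fold), Rpa2 (at least 17.5-fold), Olfr23 (at least 11.3-fold), Plagl1 (2.94 ± 0.86) and Arpc3 (2.92 ± 0.85). Ccnt2 stood at 118 ± 35.4 CPM against 1.80 ± 3.11 from 2 counts.

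Camera called 4 further lists in this comparison, each with adjusted p = 0.322 once the correlation was estimated. FGF signalling genes had 8 of 11 tested members positive (median 0.49, adjusted p = 0.0465), among them the ligand Fgf9 (127 ± 26.0 against 6.08 ± 10.5 CPM), Flrt3 (2.98 ± 1.05) and the feedback inhibitor Spry2 (3.04 ± 1.30), with 1 member higher adjusted over the list alone and 0 over all genes in edgeR. The list was made because the series title names Fgf2, so it is no independent evidence of direction. Endothelial and mural markers had 6 of 7 positive (median 1.10, adjusted p = 0.0465), with the collagen Col1a2 at 3.27 ± 1.33. Synaptic vesicle genes had 18 of 27 negative (median -0.43, adjusted p = 0.0465), with the calcium sensor Syt1 at -0.97 ± 0.34 and Cplx2 at -2.14 ± 0.82. Nuclear genes of oxidative phosphorylation had 24 of 32 negative (median -0.50, adjusted p = 0.0465), with Ndufb2 at -1.16 ± 0.46 and Sdhc at 16.2 ± 16.9 against 148 ± 122 CPM. With the scale set on the 200 most abundant genes, the synaptic vesicle median was 0.00 and that of oxidative phosphorylation -0.16, all genes moving by 0.38. In these lists other than FGF signalling, 0 members passed over the list alone or over all genes in edgeR.

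These further calls changed when libraries were left out, and the immediate early genes were called in each of the fits named here. Each such fit also let more genes through the filter, so effects of the libraries and of the filter cannot be told apart. Without mCherry 1, mCherry 2 or c-fos 1, camera called 1 list. Without c-fos 2, c-fos 3 or overlap 1 it called 2, without overlap 2 or overlap 3 it called 3, and without mCherry 3 it called 4, which were the immediate early genes, FGF signalling (adjusted p = 0.0320), synaptic vesicle genes (0.0147) and cytosolic ribosomal proteins (0.00493, higher). Endothelial and mural markers were among none of them. Without mCherry 3 and overlap 1 together it called 4, the immediate early genes, synaptic vesicle genes, cytosolic ribosomal proteins and spermatocyte markers. Spermatocyte markers, the cell type named in the labels, had an adjusted p of 0.00656 there over 5 tested genes, against 0.103 over 6 without mCherry 3 alone and 0.720 over 18 with no filter. With the filter and all libraries only 1 of these markers was tested. Their summed levels were 127, 256 and 588 CPM in mCherry 1, 2 and 3, and 348, 371 and 240 CPM in c-fos 1, 2 and 3.

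The lists not called in c-fos against mCherry had adjusted p from 0.0843 (cytosolic ribosomal proteins, median 0.40) to 0.928. With no filter on low counts and all libraries, camera called 3 lists, the immediate early genes, synaptic vesicle genes (adjusted p = 0.00156) and cytosolic ribosomal proteins (0.000109 over 85 genes, higher). With the filter and an estimated correlation, camera gave the ribosomal list an adjusted p of 0.322. Medians were -0.49 for glutamatergic neurons, 0.09 for basolateral amygdala subregions, 0.03 for striatal projection neurons, -0.16 for astrocytes, -0.32 for oligodendrocytes, -0.26 for Notch signalling and -0.58 for neuropeptides. They were -0.41 for opioid, histamine, pain and itch receptors, 0.88 for monoamine and acetylcholine receptors, -0.26 for glutamate receptors, -0.32 for GABA receptors and -0.45 for potassium channels. Sodium and calcium channels had -0.07, postsynaptic density genes -0.30, heat shock genes 0.03 and interferon genes 0.37. The median differed in sign from camera's direction for striatal projection neurons, astrocytes and heat shock genes. That of opioid, histamine, pain and itch receptors covered 9 tested genes. Summed over 33 genes with counts and scaled to total counts, these receptors stood higher in c-fos, at 1711 ± 356 against 1193 ± 203 CPM (exact permutation p = 0.1). The median is on the TMM scale, so the opposite direction may rest on the scale as well as on the genes covered. The separation of the sums need not hold on the TMM scale. The lists of GABAergic neurons, oligodendrocyte precursors, microglia, ependyma, blood cells, spermatocytes and mitochondrially encoded genes had too few tested members.

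The second comparison asked how cells carrying both labels differed from cells labelled mCherry. Meg3 and Malat1, abundant nuclear long noncoding RNAs, fell in overlap cells. Meg3 had 6869 ± 999 CPM in overlap and 15739 ± 3659 in mCherry (log2 fold change -1.20 ± 0.16), and Malat1 3307 ± 311 and 8108 ± 1092 (-1.29 ± 0.18), each with an adjusted p of 0.00631 in edgeR and lower in every overlap library than in every mCherry library. Both overlap annotated genes on the opposite strand. Immediate early genes were higher as a group, with 20 of 23 tested members positive and a median of 1.57. Camera called the list at an adjusted p of 1.04e-07, a call lost with an estimated correlation (adjusted p = 0.103). Their summed level was 4310.0 ± 109.6 CPM, 2.89-fold that of mCherry (exact permutation p = 0.1).

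These were the 2 genes that edgeR called, both lower, of 1114 with an unadjusted p under 0.05. Non-overlapping genes made up 17.4% of those tested, where chance gives 10%. Neither call stood with DESeq2 size factors, upper quartile scaling, the stricter filter, the 2 groups alone, or mCherry 3 and overlap 1 left out, each of which called 0 genes. Without mCherry 3 and overlap 1 the log2 fold changes of Meg3, overlap vs mCherry, and Malat1, overlap vs mCherry, were no smaller in size, -1.47 ± 0.27 and -1.42 ± 0.29, and their errors were larger. DESeq2 called 180 genes, 131 higher and 49 lower, with 0 of these 2 among them. With the scale set on the 200 most abundant genes, which moved all genes by 0.78, Meg3 stood at -0.38 ± 0.15 and Malat1 at -0.48 ± 0.15, and neither passed. The number called rose to 20 without mCherry 3, 16 without mCherry 1 and 5 without mCherry 2, with both genes among them each time.

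By fry the immediate early gene list had an adjusted p of 0.0132. Adjusted over the list alone, 9 members were higher and 0 over all genes in edgeR. Npas4 had 232 ± 190.0 CPM (4.76 ± 1.22), the kinase gene Sik1 233 ± 219 against 4.84 ± 4.58 (5.23 ± 1.35), and Nr4a3 225 ± 117 (2.22 ± 0.72). Atf3 stood at 117 ± 138 CPM, and Fos, whose product names a label, at 420 ± 198 (2.00 ± 0.66). Without Fos the list had an adjusted p of 4.21e-07, and 0.115 with an estimated correlation. Overlap cells carry the c-fos label too, so here as well the list is not independent of the labelling. Summed GABAergic markers stood at 598 ± 167 CPM against 342 ± 122 in mCherry (exact permutation p = 0.1).

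The genes next in rank did not pass in edgeR. Among those with lower values in overlap cells, the chaperone Hsp90ab1 had 2175 ± 614 against 5133 ± 296 CPM (-1.24 ± 0.22), the ubiquitin ligase Ttc3 1578 ± 370 against 3944 ± 461 (-1.32 ± 0.24), and Frrs1l 734 ± 139 against 2399 ± 387 (-1.70 ± 0.31). Gria2, an AMPA receptor subunit, had 1726 ± 438 against 4148 ± 1178 (-1.26 ± 0.26), with Nptxr at -1.71 ± 0.34 and Rtn1 at -1.44 ± 0.29. Genes with higher values included Fbxo8 (5.84 ± 1.31), Olfr23 (at least 25.4-fold), Ppl (4.75 ± 1.16), Cmtm8 (5.05 ± 1.27) and Fam184b (4.70 ± 1.22). Gpr107 was at 0 counts in overlap, at least 26.8-fold lower, though its mCherry level of 271 ± 379 CPM varied by more than its mean.

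With all libraries and the filter on low counts, camera called no list here other than the immediate early genes. With no filter it called 5, adding GABA receptors (adjusted p = 0.00443 over 15 genes), sodium and calcium channels (0.0406 over 35), synaptic vesicle genes (0.00169) and postsynaptic density genes (0.0303), all lower. With the filter and an estimated correlation, camera gave an adjusted p of 0.620 for postsynaptic density genes and 0.491 for each of the others added. Without overlap 1 it called 3, adding FGF signalling and synaptic vesicle genes, and without mCherry 3 and overlap 1 together 3, adding sodium and calcium channels and synaptic vesicle genes. GABA receptor genes had 10 of 10 tested members negative (median -0.88, adjusted p = 0.107 with the filter), with Gabra2 at -0.80 ± 0.32, and sodium and calcium channel genes 19 of 24 (median -0.41, adjusted p = 0.195 with the filter), with Scn2a at -1.35 ± 0.52. Fry, which sets no list against other genes, gave adjusted p of 0.0328 and 0.0409 for them. Camera with the filter and all libraries called neither, at the preset or the estimated correlation. With the scale set on the 200 most abundant genes the GABA receptor median was -0.07 and that of the channels 0.38. FGF signalling had 7 of 11 positive (median 0.73, adjusted p = 0.107), 4 of them higher adjusted over the list alone and 0 over all genes in edgeR, with Fgf9 at 4.46 ± 1.27 and Fgf18 at 2.55 ± 0.93.

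**Figure D2:**
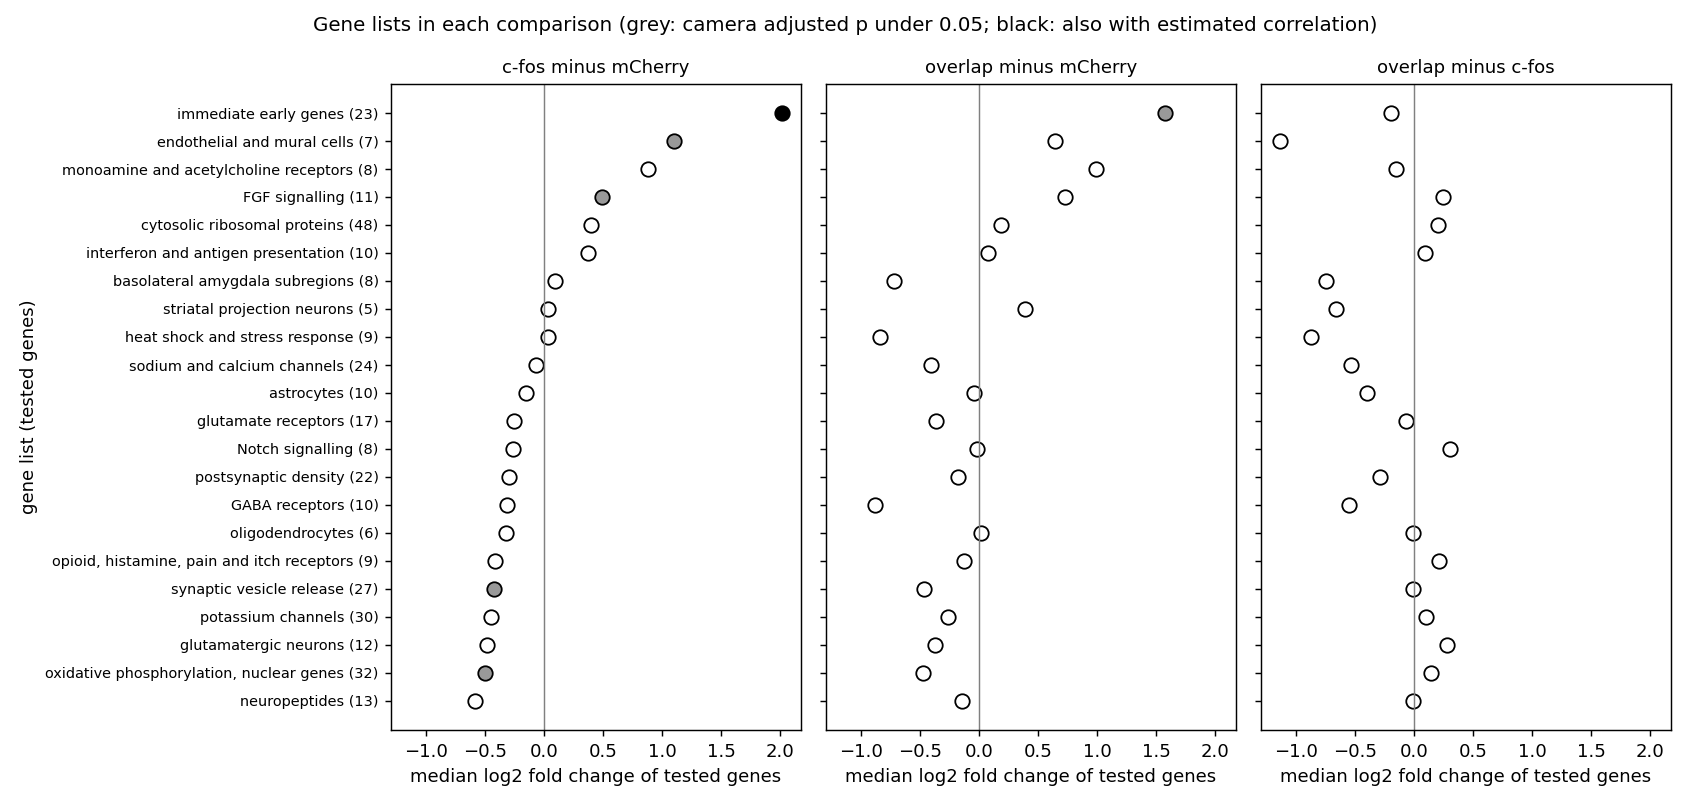
Median log2 fold change of the tested genes in each of the 22 lists tested (number of tested genes in brackets), for the 3 comparisons. Grey points passed camera at an adjusted p under 0.05 and the black point also did so with an estimated correlation. Immediate early genes lay at 2.02, 1.57 and -0.20.

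The third comparison asked how cells carrying both labels differed from cells labelled c-fos. Immediate early genes did not separate these groups, with 9 of 23 tested members positive, a median of -0.20 and a camera adjusted p of 0.913. The summed levels were 4310.0 ± 109.6 and 4429.7 ± 862 CPM (exact permutation p = 0.8). Both groups carry the c-fos label, so similar levels of these genes may follow from the labelling. The median followed the scale, at 0.01 with DESeq2 size factors, which moved all genes by 0.22, at -0.38 with upper quartile scaling, which moved them by -0.18, and at 0.22 with the 200-gene scale, which moved them by 0.41. Over the 13 other settings in which camera was run on the list, DESeq2 size factors included, it ran from -0.51 to 0.22. Fos stood at 420 ± 198 and 352 ± 42.4 CPM (0.25 ± 0.63). Hesx1 had 1 count over the 3 overlap libraries, against 218 in c-fos. Jsrp1, a gene of the muscle junctional reticulum, had 452 ± 588 CPM in overlap and 0 in c-fos, at least 56.1-fold higher, with an SD above its mean.

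EdgeR called 0 genes here, with 406 at an unadjusted p under 0.05 where chance gives 398. The smallest adjusted p was 0.158, and non-overlapping genes made up 12.6%, where chance gives 10%. DESeq2 called 6 genes and limma-voom 2. Leaving out mCherry 3, which enters only through the shared spread, filter and scaling, called 9. Leaving out mCherry 1 called 1, and leaving out mCherry 3 and overlap 1 together called 1, Hesx1. Why the count rose without mCherry 3 was not tested.

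Meg3 (-0.89 ± 0.16), Malat1 (-0.86 ± 0.17), Hsp90ab1 (-0.96 ± 0.21), the chromatin remodeller gene Chd3 (-1.03 ± 0.25), Ttc3 (-0.94 ± 0.23) and the splicing factor gene Srrm2 (-1.02 ± 0.27) had lower values in overlap cells, and Ptms a higher one (1.63 ± 0.42). Arhgef18 and Ywhah were at 0 counts in overlap, at least 14.4-fold and 11.1-fold lower. Jup (4.11 ± 1.01), Mlip (3.77 ± 1.05), Ypel1 (3.41 ± 0.97) and Ppargc1a (3.10 ± 0.93) had higher values. Negative fold changes were found for 145 of the 200 most abundant genes (median -0.41), a shift that Meg3, Malat1 and other abundant genes may share. No list was called by camera, with an estimated correlation or by fry. The smallest camera adjusted p was 0.858, shared by basolateral amygdala subregions (median -0.75), endothelial and mural cells (-1.14), GABA receptors (-0.55) and sodium and calcium channels (-0.54).

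Tested over any group difference, 3 genes passed in edgeR, Hesx1 (adjusted p = 0.0177), Meg3 (0.0186) and Malat1 (0.0186), of 817 with an unadjusted p under 0.05. DESeq2 called 76 and limma-voom 19. The count fell to 0 without c-fos 2 and to 0 without overlap 3, and reached 52 without mCherry 1, 20 without mCherry 2, 21 without mCherry 3 and 5 without overlap 2. Without mCherry 3 and overlap 1 together it was 1, Hesx1.

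The series title names Fgf2 and Notch2 as markers of separate projections, and both had too few counts for the test. Fgf2, a growth factor gene, had 5, 6 and 22 counts in the 3 c-fos libraries (46.1 ± 26.1 CPM, scaled to total counts) and 0 in every mCherry and overlap library. That is at least 13.7-fold over mCherry and 9.24-fold over overlap (exact permutation p = 0.1 for each), and edgeR without a filter gave adjusted p of 0.577 and 0.701. In all, 107 genes had counts in each c-fos library and in no other, against at most 99 for any other triple of libraries. Among genes with at least 10 counts the c-fos triple had 61 and ranked 3, the highest triple having 68. The c-fos libraries also had the most genes at equal depth, 12371 to 13221, against at most 12195 in the other 6.

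Notch2, a receptor gene, had 24, 0 and 33 counts in mCherry, 0, 1 and 0 in c-fos and 1, 2 and 0 in overlap. The mCherry to c-fos ratio of summed levels was 45.7 (95% exact interval 7.88 to 1837) and the mCherry to overlap ratio 12.8 (4.17 to 63.9), intervals that cover counting error only. The deepest library, mCherry 2, held none of the counts, exact permutation p was 0.4 for both, and edgeR without a filter gave adjusted p of 0.102 and 0.270.

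**Figure D3:**
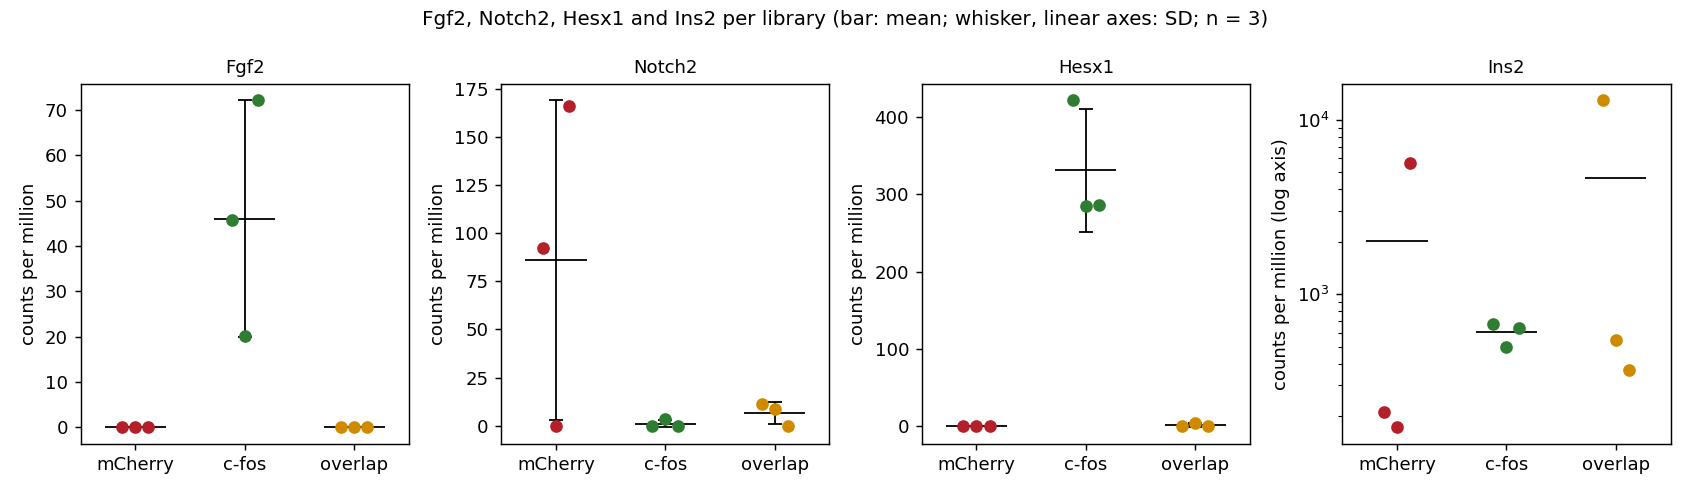
Level of Fgf2, Notch2, Hesx1 and Ins2 in each library, in CPM of the total count (points, libraries; bars, mean; whiskers on the linear axes, SD; n = 3; log axis for Ins2). Fgf2 had counts in the c-fos libraries only, and Notch2 had 24, 0 and 33 counts in mCherry.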

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

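Leaving out mCherry 3 and overlap 1 and the scale on the 200 most abundant genes were chosen after seeing the data. The similarity difference stayed positive, at 0.0561 with Pearson correlation and 0.108 with the stricter filter. That filter keeps genes by the real groups, which can raise similarity within them by construction. Its value is therefore no independent support. At its preset correlation camera called the immediate early genes in 13 of 13 further settings for both comparisons with mCherry, and in 0 for overlap against c-fos. With an estimated correlation the call was lost for overlap against mCherry, adjusted p = 0.103.

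The counts of genes changed, c-fos vs mCherry, of genes changed, overlap vs mCherry, of genes changed, overlap vs c-fos, and of genes changed, any group, were 0, 2, 0 and 3. They became 253, 344, 41 and 504 with no filter, 3, 180, 6 and 76 with DESeq2, 8, 18, 2 and 19 with limma-voom, and 1, 6, 0 and 4 with the robust fit. The stricter filter and upper quartile scaling each gave 1, 0, 0 and 1, and DESeq2 size factors 0, 0, 0 and 1. Leaving out mCherry 3 and overlap 1 gave 1, 0, 1 and 1, the 200-gene scale 0, 0, 0 and 1, and fits of 2 groups 0, 0 and 2. Without a filter, 1 library held at least as many counts as all others together for 224 of the 253 and 257 of the 344 calls against mCherry, most often mCherry 3, and for 28 of the 41 in overlap against c-fos, most often overlap 1. Other causes were not tested. Leaving out 1 replicate gave 0 to 1, 2 to 20, 0 to 9 and 0 to 52, with more genes tested, 9247 to 10174.

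Lists called were 5, 1 and 0. For c-fos against mCherry they fell to 1 with an estimated correlation, 1 with fry and 3 with no filter, and were 1 to 4 leaving out 1 replicate. For overlap against mCherry they were 0, 3 and 5 in those settings, 1 to 3 leaving out 1 replicate, and 3 without mCherry 3 and overlap 1. The cause was not tested.

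Same-numbered deviations correlated at -0.03 to 0.04, so the numbers were not taken to pair samples. With low counts and 3 libraries per group, such values cannot exclude a pairing or a shared batch. With the replicate block, edgeR called 0, 10, 3 and 10 genes, and camera 1, 1 and 0 lists. Not every sample correlated best with its own number. Of scalings, DESeq2 size factors moved the median of all genes by 0.23 in overlap against mCherry and 0.22 in overlap against c-fos, upper quartile scaling by 0.12 in c-fos against mCherry and -0.18 in overlap against c-fos, and the 200-gene scale by 0.38, 0.78 and 0.41.

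Of single genes, none passing in edgeR, Kcnk2, c-fos vs mCherry, (-2.79) turned to 0.88 with limma-voom, 1.72 without mCherry 3 and overlap 1, and -3.35 to 1.73 leaving out 1 replicate. Ndufs1, overlap vs mCherry, (-2.49) turned to 0.66 without those libraries, and ran from -4.25 to 0.24 leaving out 1 replicate. Fos, overlap vs c-fos, (0.25) turned to -0.18 without those libraries, and ran from -0.19 to 0.50 leaving out 1 replicate. Gabra2, overlap vs mCherry, turned from -0.80 to 0.000244 with the 200-gene scale, which moved all genes by 0.78. In simulated counts of this depth and spread, most changes of 8-fold or less were not called.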

Other observations

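The tests of group-private genes were chosen only after the result was seen, as was the need for a permutation p in the complexity test. Markers of many cell types were present. Summed levels in mCherry, c-fos and overlap were 2933 ± 780, 2359 ± 551 and 2294 ± 164 CPM for glutamatergic neurons, 779.9 ± 71.0, 938 ± 31.4 and 621 ± 245 for basolateral amygdala subregions, and 467 ± 163, 721 ± 138 and 436 ± 256 for striatal projection neurons. Oligodendrocyte markers stood at 4146 ± 2006, 3554 ± 709 and 3504 ± 1033 CPM, astrocyte markers at 1393 ± 113, 1624 ± 343 and 1310 ± 375, and precursors at 199.7 ± 65.4, 277 ± 79.9 and 354 ± 148. Microglial markers had 234 ± 143, 295 ± 190 and 347 ± 144 CPM, endothelial and mural markers 404 ± 184, 665 ± 257 and 467 ± 164, ependymal markers 325 ± 476, 61.2 ± 34.6 and 124 ± 75.1, and blood markers 1.28 ± 2.22, 7.68 ± 10.5 and 31.0 ± 27.6. Spermatocyte markers, the cell type in the labels, had 324 ± 238, 319.8 ± 70.4 and 329.5 ± 70.3 CPM. In every library, glutamatergic and oligodendrocyte markers lay above these, at least 1742 and 2112 CPM against at most 588. This argues against spermatocytes as the main source of the RNA, though the lists hold different genes. Over all lists the smallest exact permutation p for any group difference was 0.0286, for immediate early genes, 0.338 adjusted over the lists, an adjustment that a single list could not pass with 280 splits.

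Heat shock genes had 4901 ± 1312 CPM in mCherry, 4987 ± 71.9 in c-fos and 2814 ± 692 in overlap (exact permutation p = 0.1 for overlap against each, the smallest possible). Hsp90ab1, a member of this list, had TMM-scaled levels close to these sums in mCherry and overlap. That gene alone may therefore carry most of the difference between the sums. Camera did not call the list (adjusted p = 0.709 against mCherry and 0.889 against c-fos). Its medians of -0.84 and -0.88 became -0.05 and -0.43 with the 200-gene scale, which moved all genes by 0.78 and 0.41. Monoamine and acetylcholine receptors had 283 ± 190, 663 ± 213 and 573 ± 141 CPM (exact permutation p = 0.1 for c-fos and 0.2 for overlap against mCherry). FGF signalling genes had 518 ± 205, 1054 ± 71.9 and 1147 ± 320 CPM (exact permutation p = 0.1 for each against mCherry, and 0.0357 over the 3 groups, 0.338 adjusted).

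Insulin transcripts were far higher in mCherry 3 and overlap 1 than elsewhere. RNA or cells from pancreatic islets may be a source, since summed Iapp, Gcg, Ppy and Pyy were 6.73-fold over the highest of the other 7 in the lower of these libraries. Prss2 and Reg1, which encode no islet hormone, were also highest in overlap 1, at 777 and 333 CPM, against 176 and 25.1 in mCherry 3. The source need not be islets alone. The other 7 libraries also held insulin transcripts, at 863 to 990 CPM in c-fos. Levels were 749 and 565 in overlap 2 and 3, and 323 and 247 in mCherry 1 and 2. Leaving out 2 libraries does not remove these. How such RNA entered, and whether it came with the sample or during library making, was not tested, and no biological explanation was tested.

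Meg3, Malat1 and other abundant transcripts were lower in overlap than in mCherry. The insulin-rich libraries as the cause are argued against, since the higher of the Meg3 and Malat1 log2 fold changes was -1.42 without them, the calls ending as the errors grew. A change of scale shared by abundant transcripts may account for part of the folds: the 200 most abundant genes, without the called ones, had a median of -0.75, 180 of the 200 were negative, and setting the scale on them, which by construction moves every gene by about as much, took Meg3 from -1.20 ± 0.16 to -0.38 ± 0.15 and Malat1 from -1.29 ± 0.18 to -0.48 ± 0.15, still below 0 by more than their errors but no longer past the threshold. Molecular complexity as the cause cannot be told apart from chance in 9 libraries: genes at equal depth were 10949 ± 1205 in overlap and 11056 ± 1521 in mCherry (exact permutation p = 0.9), with r = 0.542 within groups (exact permutation p = 0.546), Spearman's rho 0.267 (exact permutation p = 0.639), and r = 0.145 without the 2 libraries farthest from the median. A difference between the labelled cells stays open and untested.

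Fgf2 belongs to 107 genes with counts in each c-fos library and in no other. That number ranked 1 among the 84 triples of libraries, and 3 among genes with at least 10 counts (61, against 68 for the highest triple), and the c-fos group was singled out after the counts were seen. Deeper sequencing as the whole cause is argued against, since the 15 triples at least as deep in their shallowest, middle and deepest library had a median of 39 such genes (24 to 99), 14 of them below 107 by more than 2 counting errors. Each of these triples holds at least 2 of the libraries mCherry 2, c-fos 2 and c-fos 3, so they are not independent checks. Chance in low counts cannot be told apart from a group difference on this, since the next triple, mCherry 2 with c-fos 2 and c-fos 3, had 99, within counting error of 107. The c-fos libraries also held the most genes at equal depth (exact permutation p = 0.1 against each group), which was not tested as a cause, and a difference between the labelled cells stays open and untested.

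Other splits of the samples were fitted in the same way. Of 10 splits of the 6 samples, 10 called as many genes as c-fos against mCherry (0, highest other 0), 1 as many as overlap against mCherry (2, highest other 0) and 10 as many as overlap against c-fos (0, highest other 0). For lists the numbers were 1 (5, highest other 1), 2 (1, highest other 1) and 10 (0, highest other 0). These splits are too few for a share under 0.05. For any group, 5 of 100 splits of the 9 samples called as many as the 3 genes, the highest other calling 4, so chance is not excluded.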
